A study of Mus musculus with 6 samples.

How the data were processed

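Gene expression had been measured in mouse embryonic fibroblasts on Illumina Mouse-6 V1 bead arrays, with biotin-labelled total RNA and 1 array per sample, per the labels. The 6 samples formed 3 groups of 2: wild-type cells, cells lacking IKKa, and reconstituted cells labelled as carrying IKKa again. Groups and replicate numbers were taken from the sample titles. Per the file headers, each deposited array file was exported from BeadStudio 1.5.0.34 with no normalization and no error model. Each held 46120 targets with 1 average bead intensity per target. The intensities in the deposited files were all positive, and no background had been subtracted as far as the values show. The deposited series matrix held a second set of intensity values. Set against the array files, these were the raw intensities after quantile normalization on a linear scale, with column medians between 116.52 and 116.62. How the authors made that matrix is not given in the sources used here.

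Targets were named through the annotation of the matrix probes. Of the 46120 targets, 46116 were matched to 1 matrix probe by their 6 values, to 6 decimals, after each raw value was replaced by the matrix value of the same rank, and 4 were not. As a check of that match, 2491 of 2575 targets with a gene number in their name (96.74%) and 3927 of 3927 with an accession in their name (100%) carried the same identifier in the annotation. A single gene symbol was given for 29534 targets, several for 11 and none for 16575, and no gene was named from a target with several. Of the single-symbol targets, 29476 had a gene identifier in the reference gene table, which changed 0 symbols. That table is of assembly GRCm38.p6. The array files name no build, so the table was used only for names and for the order of neighbouring genes.

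The array files hold no detection values, so the background correction chosen before the data were examined, which reads negative controls from them, was replaced. The nec function of limma 3.58.1 (R 4.3.3) was given 394 background probes as negative controls, with an offset of 16. These were 352 targets for immune-receptor gene segments and 42 spike or non-mouse control targets. Quantile normalization and log2 transformation followed. A probe counted as detected on an array where under 1% of the background probes were at or above its signal, and probes detected on at least 2 of the 6 arrays were tested. Control, construct and numbered targets were left out of the tests of genes. This left 11659 probes for 7407 named genes. Signal over background set the depth of each array: median signals lay between 111.1 and 123.1 intensity units and medians of the background probes between 100.8 and 114.45. The number of arrays limits the precision.

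Linear models with group means were fitted to all 6 arrays with lmFit and eBayes of limma, which left 3 residual degrees of freedom and a prior of 4.01. Each of 3 comparisons was tested two-sided with Benjamini-Hochberg adjustment, and an adjusted p under 0.05 was called. For a probe below background on every array of a group, the fold is a bound. It sets the mean of the bright group against the dim group's mean, over its arrays, of the higher of the lowest signal above background on that array and the probe's own signal. No fold is given where that bound is under 1. A gene with several probes was represented by the probe with the highest mean over the 6 arrays. The labels do not say that the samples came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

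The comparisons, the alternatives to be tried, the rule for named genes and the gene lists were fixed before the data were examined. The rule took, per comparison, the 12 largest rises and the 12 largest falls among called genes with a proper symbol whose groups did not overlap. It also took the 10 genes per direction with the largest smaller change among genes differing both ways, up to 4 called members of each list, up to 2 members as values where none was called, and Actb and Gapdh. Chuk, the gene of IKKa, was always to be named, and is not analysed here because no probe carries its symbol in the annotation used. There were 22 gene lists and 8 lists of cell type markers. Members of a list were tested as a set with camera (preset correlation 0.01, 1 probe per gene, against the 7407 genes), adjusted over 22 lists and 3 comparisons together. The other 8 lists, the sex-linked genes and all cell type markers except those of fibroblasts, had fewer than 5 tested members and were only described. Camera was repeated with an estimated correlation, a setting in which it rests on the 3 residual degrees of freedom. The fry test, which asks whether a list's own genes move one way on balance, was run as an alternative.

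The fit was tested on simulated data, with 200 of 11659 probes changed in each of 20 draws per comparison. In IKKa-null against wild type, 98.3% of 4-fold, 42.1% of 2-fold and 2.5% of 1.5-fold changes were recovered, none with the wrong sign. The corresponding shares were 98.0%, 42.5% and 3.0% for reconstituted against IKKa-null, and 98.4%, 44.1% and 2.3% for reconstituted against wild type. In the data far larger shares of the probes were called (29.0%, 13.4% and 36.4%). The adjusted threshold is then less strict, so the simulated shares are not those recovered in the data. Of the calls, 7.0%, 6.9% and 7.4% were false in the 3 comparisons, above the nominal 5%. A first version with 1 draw had been replaced by these 20 draws, and the bound for passing was changed at the same time. A second simulation was added after that was seen, for IKKa-null against wild type with variances drawn from the fitted prior, and 4.6% of its calls were false. In simulated lists of 20 genes, 20 of 20 shifted by 0.5 on the log2 scale and 0 of 20 unshifted lists were called. The simulated probes varied independently of each other, so this says nothing about false calls in lists whose genes vary together.

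The alternatives were no background correction, normexp with an offset of 50, median scaling, cyclic loess, no filter on dim probes, detection on all 6 arrays, the series matrix values, only the compared groups in the fit, a trended and robust eBayes, stricter thresholds, the replicate number as a block, and leaving out each array in turn. A group left with 1 array was then assumed to vary like the others. Lists were also run with the mean of all probes of a gene. Using the spike controls alone as negatives, and list medians from arrays of 1 replicate number, were added after the data had been seen. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used for reading and plotting.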

Results

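Expression was profiled in mouse embryonic fibroblasts, connective tissue cells grown in serum-containing medium, from 3 groups of 2 samples each: wild type, IKKa-null and reconstituted. IKKa, the product of Chuk, is a kinase of the NF-kB pathway, and the series asks which genes it regulates. Chuk itself is not analysed here, so the targeted gene gave no check of the labels. Across probes, which are not independent replicates, the 2 replicates correlated with r = 0.9794 in wild type, 0.9745 in IKKa-null and 0.9682 in reconstituted cells. The SD of the log2 difference between replicates was 0.38, 0.413 and 0.469 in the same order.

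Wild-type cells differed from both other groups in sequences of vectors and viruses and in sex-linked genes. The target for SV40 large T antigen, a viral protein that binds p53 and the retinoblastoma protein, gave 5254 ± 1163 intensity units in wild type (mean ± SD, n = 2). It gave 100.2 ± 16.4 in IKKa-null cells, within background, and 207.8 ± 6.4 in reconstituted cells, above background on both arrays. The neomycin resistance target gave 112.2 units in wild type, 2332 in IKKa-null and 3048 in reconstituted cells. The ampicillin resistance target gave 621.2, 116.0 and 143.6. Xist, the RNA of the inactive X chromosome, was lower in IKKa-null than in wild-type cells by at least 5.79-fold (limma adjusted p = 0.00044). The Y-linked genes Eif2s3y and Kdm5d were higher by at least 4.44-fold and at least 1.24-fold (adjusted p = 7.36e-05 and 0.000921). Between IKKa-null and reconstituted cells neither Xist, within background in both, nor Eif2s3y (-0.34 on the log2 scale) was called (adjusted p = 0.98 and 0.223). Those 2 groups also differed in viral sequence: the 5' long terminal repeat of Moloney murine sarcoma virus gave 3393 units in IKKa-null and 255.8 in reconstituted cells, an 18.75-fold difference after normalization (adjusted p = 6.82e-05), and 106.7 in wild type.

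**Figure D1:**
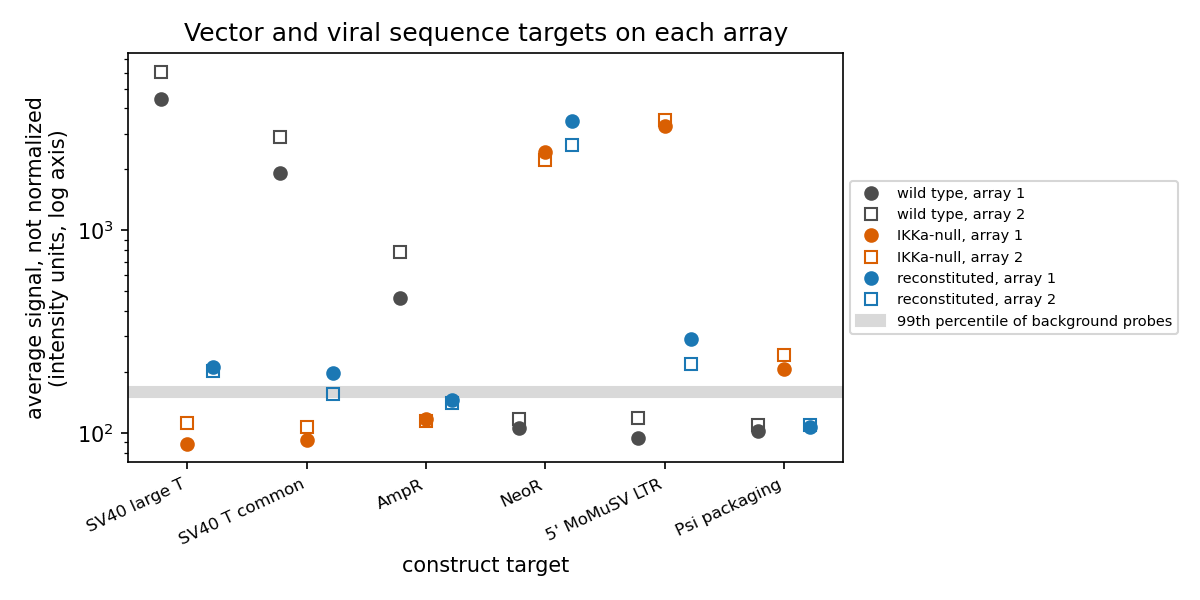
Average signal, not normalized, in intensity units on a log axis, for 6 vector and viral targets on each of the 6 arrays (filled circles, replicate 1; open squares, replicate 2; colours, groups; grey band, the 99th percentile of background probes, 150.3 to 169.0). Large T lies at 4432 and 6076 units in wild type and at 212.3 and 203.2 in reconstituted cells.

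The first comparison asked which genes differed between IKKa-null and wild-type cells. These cells also differed in sex-linked genes and in large T, so absence of IKKa cannot be told apart from those differences. Rhox5, an X-linked homeobox gene, gave a log2 signal of 12.88 ± 0.03 in IKKa-null against 5.07 ± 0.005 in wild-type cells (mean ± SD, n = 2), at least 97.9-fold higher (SE of the log2 change 0.169, adjusted p = 6.59e-06). Mgmt, a DNA repair methyltransferase, rose by at least 22.0-fold, Mgp, an inhibitor of calcification, by at least 23.6-fold, and Blnk, an adaptor of B cell receptor signalling, by at least 15-fold. Klra4, of a lectin receptor family whose members may share probe sequence, rose by at least 20.4-fold and is uncertain for that reason. Glipr1, Mgst2, Xdh, Cyp2c55 and Thbd rose by at least 29.3-fold, 10.9-fold, 11.1-fold, 12.6-fold and 13.8-fold, and Psca 21.9-fold. Ifi27l2a rose 30.8-fold, but 16.9-fold and 54.96-fold without IKKa-null replicates 1 and 2, at least 18.3-fold without wild-type replicate 1 and 17.9-fold without wild-type replicate 2. Genes were ranked by normalized signal, so where a group lay within background the order of the rises and falls is not measured. In this comparison the dimmer group was above background on 1 of its 2 arrays for Ifi27l2a, Cyp1b1, Birc2, Fosb, Cd14 and Prl2c4. Hspb1, a small heat shock protein, fell by at least 45.6-fold, from 11.51 ± 0.19 to 4.77 ± 0.16 (adjusted p = 3.09e-05). Cyp1b1, a cytochrome P450, was 24.2-fold lower, and Pdpn, a membrane glycoprotein of stromal cells, at least 10.2-fold lower. The transcription factors Sox11, Sox12 and En1 were at least 8.31-fold, 5.58-fold and 9.32-fold lower. Tiam1, Hap1, Ddah2, Smpdl3b, Slc38a4 and Rnf130 made up the rest of the 12 largest falls.

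The p53 target genes were called higher as a list. The list as fixed also named Cdkn2a and Trp53, which are genes of the p53 pathway rather than targets of p53. Of 15 tested, 7 rose and 1 fell (7 and 1 adjusted over the list alone), with a median log2 change of 0.96 and a camera adjusted p of 0.000452 (adjusted p = 0.653 with an estimated correlation). Cdkn1a, the cell cycle inhibitor p21, rose 6.91-fold (2.79 ± 0.222, log2 change ± SE, adjusted p = 0.000404), and Ccng1 rose 6.39-fold. Trp53inp1 and Pmaip1, which act in cell death, rose by at least 4.86-fold and at least 2.05-fold. The wild-type cells of this comparison were those with the large T signal.

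DNA replication and G1/S genes fell. Of 29 tested, 15 fell and 2 rose (17 and 2 adjusted over the list alone), with a median of -0.75 and a camera adjusted p of 0.0032 (adjusted p = 0.653 with an estimated correlation). Cdc6 and Mcm7, of the replication licensing machinery, fell by 1.41 and 1.34 on the log2 scale (adjusted p = 0.00163 and 0.00187), whereas Ccnd1, cyclin D1, rose 4.86-fold. Among 20 mitosis genes, 8 fell and 1 rose (12 and 1 adjusted over the list alone), with a median of -0.53 and a camera adjusted p of 0.0252 (adjusted p = 0.653 with an estimated correlation). Pttg1, securin, fell by 1.88, and Plk1, a mitotic kinase, rose by 2.26. The mitosis call was lost without IKKa-null replicate 1 (median -0.52), under median scaling (-0.38) and among probes detected on all 6 arrays (-0.51).

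Matrix proteases and inhibitors rose, with 5 of 14 higher and 0 lower (5 and 0 adjusted over the list alone), a median of 0.59 and a camera adjusted p of 0.00642 (adjusted p = 0.653 with an estimated correlation). The gelatinase Mmp2 rose 3.86-fold and the membrane-bound Mmp14 2.37-fold (adjusted p = 0.00213 and 0.00408). Of 21 glycolysis and hypoxia genes, 4 rose and 0 fell (4 and 0 adjusted over the list alone), with a median of 0.48 and a camera adjusted p of 0.0204 (adjusted p = 0.825 with an estimated correlation). That call was lost without IKKa-null replicate 1 (median 0.27), without wild-type replicate 2 (0.44) and under median scaling (0.60). Its highest member, Pdk1, rose by 1.49 and was not called without IKKa-null replicate 1 (0.97) or wild-type replicate 2 (1.08), or with no filter on dim probes.

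NF-kB target genes gave 5 higher and 0 lower of 24 (5 and 0 adjusted over the list alone), with a median of 0.57 and a camera adjusted p of 0.0225 (adjusted p = 0.825 with an estimated correlation). Birc2 and Birc3, inhibitors of apoptosis, rose 12.7-fold and at least 3.50-fold (adjusted p = 0.00027 and 0.000138), and Tnfaip2 rose 6.65-fold. Birc2 and Birc3 are paralogs, and whether their probes share transcripts was not tested. They are neighbours on chromosome 9 in the GRCm38.p6 gene order. The next tested genes, Yap1, Cfap300 and Cep126, named after their values were seen, rose 8.74-fold, at least 7.12-fold and at least 1.61-fold. The list's direction turned without IKKa-null replicate 1 (median -0.53). Its call was also lost without wild-type replicate 2 (0.12), with cyclic loess (0.71) and among probes detected on all 6 arrays (0.51). The median was 1.27 without wild-type replicate 1 and 2.26 without IKKa-null replicate 2. Within each group, NF-kB targets were brighter on the array numbered 1 than on that numbered 2, by a median of 0.76 in wild type, 2.31 in IKKa-null and 2.22 in reconstituted cells. Nfkbia, an inhibitor of NF-kB that is itself induced by it, gave log2 signals of 9.10, 9.95 and 10.58 on the arrays numbered 1 of the 3 groups, and 7.77, 5.99 and 5.69 on those numbered 2.

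**Figure D2:**
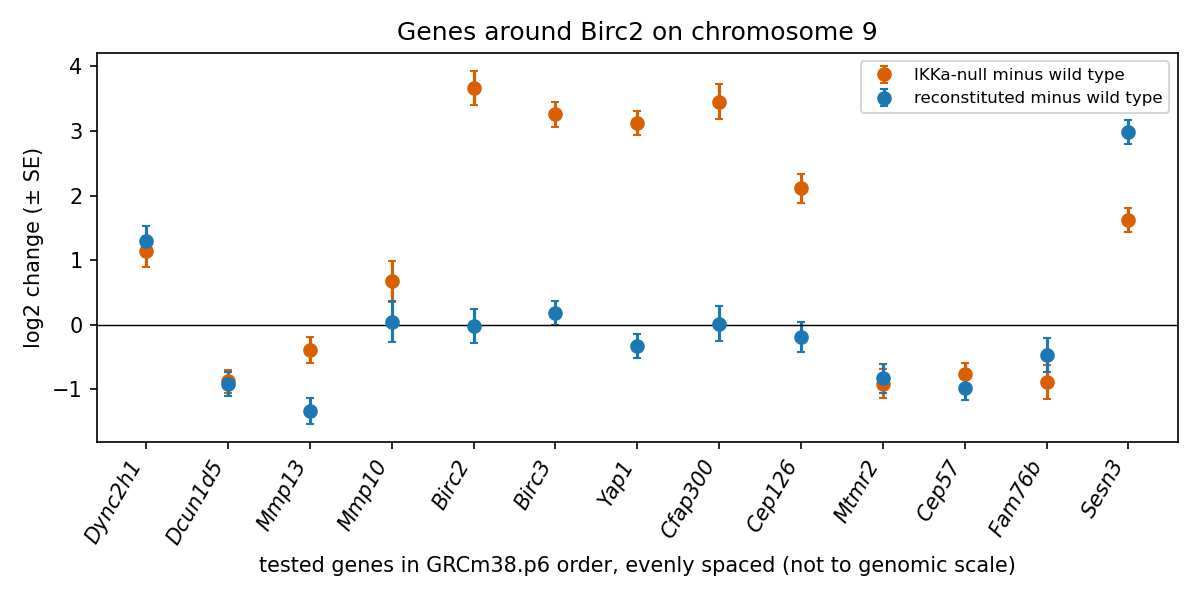
Log2 change (± SE, 2 arrays per group) of 13 genes of chromosome 9 in GRCm38.p6 order, evenly spaced and not to genomic scale, in IKKa-null minus wild type (orange) and reconstituted minus wild type (blue). Yap1, above background on all arrays, lies at 3.13 and -0.33, whereas Birc3, Cfap300 and Cep126 were within background outside IKKa-null cells, Dync2h1 in wild type and Mmp13 in reconstituted cells, so points that use those groups are no measured sizes.

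**Figure D3:**
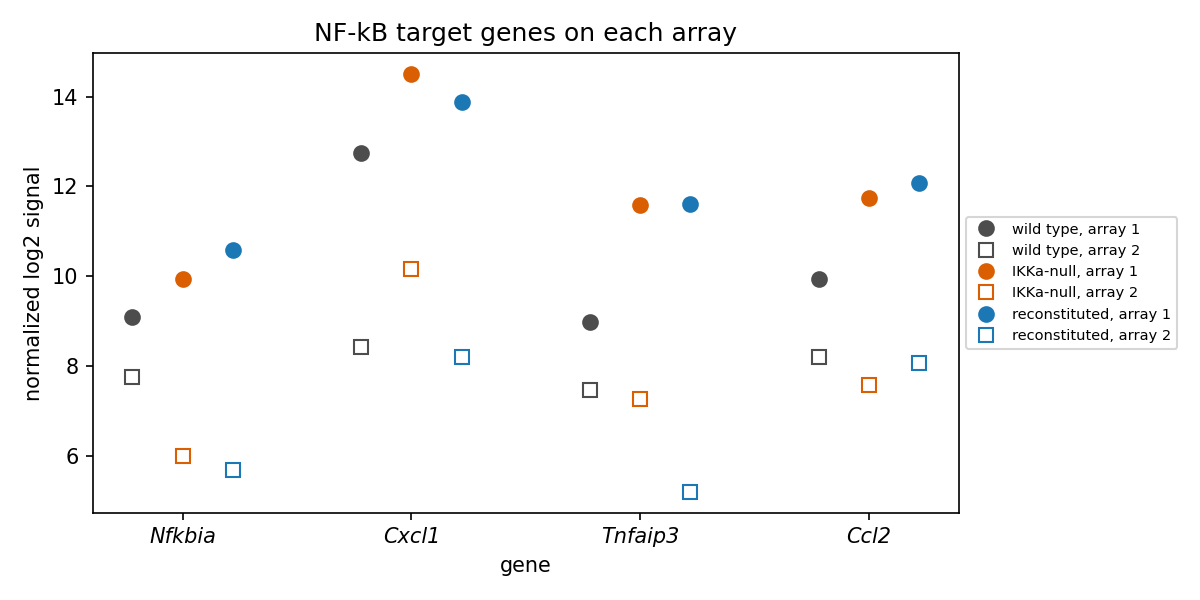
Normalized log2 signal of 4 NF-kB target genes on each array (filled circles, replicate 1; open squares, replicate 2; colours, groups). Over the groups these 4 differed between the numbers by means of 3.295 (Ccl2) to 4.776 (Cxcl1), more than the list medians of 0.76 to 2.31. Cxcl1 lies at 12.74, 14.51 and 13.88 on the arrays numbered 1 of wild type, IKKa-null and reconstituted cells, and at 8.42, 10.17 and 8.21 on those numbered 2.

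Interferon-stimulated genes rose, with 5 of 16 higher and 0 lower (5 and 0 adjusted over the list alone), a median of 1.13 and a camera adjusted p of 0.00341 (adjusted p = 0.825 with an estimated correlation). Ifit3 rose by at least 5.79-fold and Trim30a by at least 1.82-fold (adjusted p = 0.0031 and 0.00643). Those bounds were 3.55-fold and 1.21-fold without IKKa-null replicate 1 and 9.35-fold and 2.74-fold without IKKa-null replicate 2. The call was lost without IKKa-null replicate 1 (median 0.57) and without wild-type replicate 2 (0.55), and the median was 1.75 without IKKa-null replicate 2. All 16 members were brighter on the array numbered 1 in wild-type and in IKKa-null cells, by medians of 1.25 and 1.29, and 3 of 16 were brighter on it in reconstituted cells (median -0.22). In IKKa-null minus wild-type cells the list's median was 1.133 on the arrays numbered 1 and 1.039 on those numbered 2, with 1 array per group in each. Immediate early genes gave 4 higher and 0 lower of 19 (4 and 0 adjusted over the list alone), with a median of 0.89 and a camera adjusted p of 0.00642 (adjusted p = 0.825 with an estimated correlation). Fosb rose 2.79-fold (adjusted p = 0.00246). That call was lost without IKKa-null replicate 1 (median 0.07), the median was 1.495 without IKKa-null replicate 2, and the arrays numbered 1 differed from those numbered 2 by -0.23 in wild-type, 0.84 in IKKa-null and 1.06 in reconstituted cells. With fry, the NF-kB, interferon, immediate early and glycolysis lists were not called.

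The other lists were not called in IKKa-null against wild-type cells. IKK and NF-kB pathway members gave 2 higher and 2 lower of 13 (2 and 2 adjusted over the list alone, camera adjusted p = 0.667). Of 5 noncanonical NF-kB targets, which depend on the IKKa branch of the pathway, 3 were lower (3 adjusted over the list alone, adjusted p = 0.134), with the chemokine Cxcl12 5.46-fold lower. That list was called under median scaling (median -1.22). Antigen presentation genes gave 2 higher and 1 lower of 10 (2 and 1 adjusted over the list alone, adjusted p = 0.6). Collagens and matrix proteins gave 6 higher and 8 lower of 26 (7 and 9 adjusted over the list alone, adjusted p = 0.979). Their median and mean, -0.05 and -0.10, were below 0 while camera put the list above other genes. Col18a1 rose 11-fold and Sparc at least 5.44-fold, and Nid2 and Col4a1 were 6.73-fold and 4.28-fold lower. Smooth muscle and myofibroblast genes gave 0 higher and 1 lower of 9 (0 and 1 adjusted over the list alone, adjusted p = 0.622), with a median of 0.23 and a mean of -0.07. The 1 was Acta2, smooth muscle actin, 7.59-fold lower (4.31-fold and 13.3-fold without IKKa-null replicates 1 and 2). Nrf2 and glutathione genes gave 6 higher and 2 lower of 19 (6 and 2 adjusted over the list alone, adjusted p = 0.103), among them Gstm1, 5.54-fold higher. The Nrf2 list was called without wild-type replicate 2 (median 0.51, against 0.28) and with fry, which also called the ribosomal proteins.

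TGF-beta and BMP response genes gave 4 higher and 3 lower of 19 (4 and 4 adjusted over the list alone, adjusted p = 0.791), with a median of -0.26 and a mean of 0.04. Fst, follistatin, rose 5.63-fold and Bmp4 3.18-fold. Wnt response genes gave 2 higher and 0 lower of 11 (2 and 0 adjusted over the list alone, adjusted p = 0.251). Cholesterol synthesis genes gave 2 higher and 3 lower of 18 (0 and 0 adjusted over the list alone, adjusted p = 0.425). For unfolded protein and amino acid stress genes the counts were 0 higher and 1 lower of 22 (0 and 1 adjusted over the list alone, adjusted p = 0.899). Ribosomal proteins gave 2 higher and 1 lower of 28 (2 and 1 adjusted over the list alone, adjusted p = 0.631). Hox and positional genes gave 4 higher and 2 lower of 17 (5 and 2 adjusted over the list alone, adjusted p = 0.58), with a median of -0.07 and a mean of 0.14. Hoxc6 rose by at least 6.35-fold and Hoxb9 was 5.21-fold lower. Imprinted genes gave 6 higher and 3 lower of 11 (6 and 3 adjusted over the list alone, adjusted p = 0.275), with Ndn 8.22-fold and Igf2 3.23-fold higher and Cdkn1c lower by at least 2.49-fold. Fibroblast markers gave 2 higher and 2 lower of 10 (2 and 2 adjusted over the list alone, adjusted p = 0.925), with a median of 0.23 and a mean of -0.11. Pdgfra, a growth factor receptor of fibroblasts, was 4.86-fold lower.

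Markers of other cell types were few among the tested genes. Of 4 epithelial markers 1 rose and 1 fell, Krt7 by at least 4.69-fold and Krt14 by 1.85 on the log2 scale. Of 3 skeletal muscle markers 1 rose and 1 fell, of 3 chondrocyte and osteoblast markers 2 rose, and of 2 endothelial markers Eng rose and Flt1 fell. Of 2 neural and glial markers 1 was lower, and neither the 1 adipocyte marker (Lpl, -0.01) nor the 1 macrophage and blood marker (Cd14, 1.24, adjusted p = 0.0692) was called. Cd14 was called without wild-type replicate 2 (1.88), and the sign of Lpl turned without wild-type replicate 1 (0.40) and IKKa-null replicate 2 (0.04) and under median scaling (0.10) and cyclic loess (0.09). All 3 sex-linked genes tested were called. Actb and Gapdh changed by -0.60 and 0.18 on the log2 scale (adjusted p = 0.0395 and 0.497), and Actb was not called under median scaling (-0.39) or cyclic loess (-0.47), or with no filter on dim probes. It also lost its call without wild-type replicate 1 (-0.49) or 2 (-0.71), IKKa-null replicate 1 (-0.56) or 2 (-0.66), or reconstituted replicate 2 (-0.59).

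Over all 11659 probes tested, 1746 were higher and 1637 lower in IKKa-null cells (29.0%), and 1108 and 717 of them differed by at least 2-fold. At least 1 probe was higher for 1112 genes and lower for 1275. Of 1748 genes with several probes, 251 had all probes called the same way and 492 had a call that not all probes shared. Among the latter, 9 had probes called in opposite directions. Higher and lower probes numbered 1066 and 571 without wild-type replicate 1, 892 and 465 without wild-type replicate 2, 869 and 643 without IKKa-null replicate 1, and 822 and 674 without IKKa-null replicate 2. The higher share of the calls was 51.6%, and 70.3% (1333 and 562) under median scaling. That scaling moved the median log2 change of all probes from -0.07 to 0.04 here, from -0.01 to -0.17 in reconstituted against IKKa-null cells and from -0.08 to -0.13 in reconstituted against wild-type cells.

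The second comparison asked which genes differed between reconstituted and IKKa-null cells, which also differed in viral sequence. Esm1, a proteoglycan better known from endothelium, rose from 4.69 ± 0.02 to 10.97 ± 0.25 (log2 signal, mean ± SD, n = 2), at least 31.4-fold (SE 0.187, adjusted p = 2.05e-05). Pdpn rose by at least 23.5-fold, and Thy1 and Pdgfra, surface proteins of fibroblasts, rose 39.5-fold and 18.5-fold (adjusted p = 0.00041 and 6.96e-05). Dcn, the matrix proteoglycan decorin, rose 21.4-fold, Dkk3, a secreted protein of the dickkopf family, 18.0-fold and Acta2 17.9-fold (10.1-fold and 31.4-fold without IKKa-null replicates 1 and 2). Crabp1, Foxs1, Slc14a1, Zic1 and Cyp1b1 were the rest of the 12 largest rises. Rhox5 fell by at least 102.4-fold to 5.84 ± 0.15 (adjusted p = 1.36e-05), Glipr1 by at least 30.7-fold, and Ndn, an imprinted gene of the necdin family, by 5.87 on the log2 scale, a 58.3-fold difference (at least 31.8-fold without reconstituted replicate 1). Aldh1a1 and Aldh1a7, aldehyde dehydrogenases, were lower by at least 12.1-fold and at least 5.64-fold, and Wnt9a was 18.3-fold lower. The prolactin-family genes Prl2c2, Prl2c3 and Prl2c4 fell by 3.99, 3.79 and 3.97, but their sequences are close enough for probes to share transcripts. Erfe, S100a7a and Hoxc6 completed the 12 largest falls. Here the dimmer group was above background on 1 of its 2 arrays for Foxs1, Cyp1b1, Ndn, Wnt9a, Prl2c4, Birc2, Bcl2l1, Tm7sf2, Prrx1, Igf2 and Lpl.

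p53 target genes fell in this comparison. Of 15 tested, 7 fell and 0 rose (11 and 1 adjusted over the list alone), with a median of -0.78 and a camera adjusted p of 0.000452 (adjusted p = 0.653 with an estimated correlation). Mdm2, the ligase that degrades p53, was 5.07-fold lower, and Cdkn1a 3.25-fold lower (adjusted p = 0.000911 and 0.00402). In the same cells the large T target was higher by at least 1.79-fold than in IKKa-null cells, where it was within background (adjusted p = 0.00183). It was still 47.0-fold lower than in wild type.

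Cholesterol synthesis genes rose, with 3 of 18 higher and 0 lower (9 and 1 adjusted over the list alone), a median of 0.55 and a camera adjusted p of 0.00124 (adjusted p = 0.668 with an estimated correlation). Tm7sf2, a sterol reductase, rose 3.57-fold and Lss, lanosterol synthase, 3.01-fold (adjusted p = 0.0013 and 0.0023). Fibroblast markers gave 4 higher and 0 lower of 10 (5 and 0 adjusted over the list alone), with a median of 0.66 and a camera adjusted p of 0.00394 (adjusted p = 0.653 with an estimated correlation). Collagens and matrix proteins gave 8 higher and 2 lower of 26 (12 and 3 adjusted over the list alone), with a median of 0.44 and a camera adjusted p of 0.0196 (adjusted p = 0.825 with an estimated correlation). Thbs2, thrombospondin 2, rose by at least 3.16-fold, whereas the basement membrane collagens Col4a2 and Col4a1 were 12.3-fold and at least 4.48-fold lower. The collagen call was lost without IKKa-null replicate 2 (median 0.38), and the median was 0.68 without IKKa-null replicate 1.

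Nrf2 and glutathione genes fell, with 6 of 19 lower and 0 higher (9 and 0 adjusted over the list alone), a median of -0.64 and a camera adjusted p of 0.0146 (adjusted p = 0.653 with an estimated correlation). Gstm2 was 7.23-fold lower and Mgst1 lower by at least 1.60-fold (adjusted p = 0.000421 and 0.00221). The median was -0.41 without reconstituted replicate 1, and the call was lost among probes detected on all 6 arrays (-0.31). Interferon-stimulated genes fell with 1 of 16 lower and 0 higher (1 and 0 adjusted over the list alone), a median of -1.13 and a camera adjusted p of 0.00394 (adjusted p = 0.825 with an estimated correlation). The 1 gene, the GTPase Irgm1, fell by 1.91 and was not called without IKKa-null replicate 1 (-1.51). Nor was the list called without that array (median -0.61), and the median was -1.84 without IKKa-null replicate 2. With fry, neither the interferon list nor the collagen list was called.

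The remaining lists were not called in reconstituted against IKKa-null cells. NF-kB target genes gave 0 higher and 4 lower of 24 (0 and 5 adjusted over the list alone, camera adjusted p = 0.0568), with Birc2, Birc3 and Bcl2l1 lower by 12.9-fold, at least 3.66-fold and 3.77-fold. The list was called without IKKa-null replicate 2 (median -1.81, against -0.52) or reconstituted replicate 1 (-2.10), under median scaling (-0.78), without background correction, with normexp, with no filter and with the series matrix values. Of 5 noncanonical targets 1 rose (1 adjusted over the list alone, adjusted p = 0.187), Cxcl12, by 3.56-fold, and the list was called without reconstituted replicate 2 (median 0.99). IKK and NF-kB pathway members gave 1 higher and 2 lower of 13 (1 and 4 adjusted over the list alone, adjusted p = 0.791). Their median and mean were above 0 (0.15 and 0.01) while camera put the list below other genes. Antigen presentation genes gave 0 higher and 1 lower of 10 (0 and 0 adjusted over the list alone, adjusted p = 0.144), and were called without IKKa-null replicate 2 (median -0.76) and with no filter. DNA replication and G1/S genes did not rise again: 0 were higher and 1 lower of 29 (0 and 0 adjusted over the list alone, adjusted p = 0.631). Mitosis genes gave 0 higher and 1 lower of 20 (0 and 1 adjusted over the list alone, adjusted p = 0.219). Smooth muscle and myofibroblast genes gave 1 higher, Acta2, and 0 lower of 9 (1 and 0 adjusted over the list alone, adjusted p = 0.631), with a median of -0.15 and a mean of 0.32. Matrix proteases and inhibitors gave 0 higher and 2 lower of 14 (0 and 3 adjusted over the list alone, adjusted p = 0.738).

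Immediate early genes gave 0 higher and 1 lower of 19 (0 and 0 adjusted over the list alone, adjusted p = 0.979). Their median and mean were above 0 (0.12 and 0.02) while camera put the list below other genes. The immediate early list was called lower without IKKa-null replicate 2 (median -0.71). TGF-beta and BMP response genes gave 3 higher and 3 lower of 19 (4 and 8 adjusted over the list alone, adjusted p = 0.58), with Tgfbi 13.6-fold higher and Bmp4 and Fst 6.56-fold and 4.49-fold lower. Wnt response genes gave 2 higher and 0 lower of 11 (3 and 1 adjusted over the list alone, adjusted p = 0.221). For unfolded protein and amino acid stress genes the counts were 2 higher and 1 lower of 22 (2 and 1 adjusted over the list alone, adjusted p = 0.977). None of 21 glycolysis and hypoxia genes or 28 ribosomal proteins was called by limma (0 and 0 adjusted over the list alone, adjusted p = 0.977 and 0.979). For ribosomal proteins the median was 0.01 and the mean -0.02. Their largest changes were P4ha1, -0.92, and Rpl22, -0.62 (adjusted p = 0.0807 and 0.12), and P4ha1 was called without reconstituted replicate 2 (-1.36). Hox and positional genes gave 4 higher and 3 lower of 17 (5 and 5 adjusted over the list alone, adjusted p = 0.791), with Prrx1 3.83-fold higher and Hoxc6 lower by at least 6.64-fold. Imprinted genes gave 2 higher and 4 lower of 11 (4 and 5 adjusted over the list alone, adjusted p = 0.631), with a median of 0.33 and a mean of -0.52, and Igf2 and Snrpn 5.72-fold and 5.54-fold lower. With fry, the imprinted and mitosis lists were called.

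Of 4 epithelial markers 3 fell, Krt7 by at least 4.90-fold and Krt19 by at least 2.65-fold. The 1 adipocyte marker, Lpl, was 3.52-fold lower and was not called without IKKa-null replicate 1 (-1.75) or replicate 2 (-1.86). Of 3 skeletal muscle markers 1 rose, of 3 chondrocyte and osteoblast markers 1 fell (Ogn, at least 2.28-fold), and of 2 endothelial markers 1 rose. Neither the 1 macrophage and blood marker nor the 2 neural and glial markers nor the 3 sex-linked genes were called. Actb and Gapdh changed by 0.17 and 0.00 (adjusted p = 0.575 and 1.0), with Gapdh at -0.08 under median scaling. It was also below 0 without wild-type replicate 1 (-0.004) or 2 (-0.004), IKKa-null replicate 2 (-0.01) or reconstituted replicate 2 (-0.11).

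In all, 755 probes were higher and 804 lower in reconstituted than in IKKa-null cells (13.4%), with 514 and 498 of them at least 2-fold apart. At least 1 probe was higher for 546 genes and lower for 617. Of 1748 genes with several probes, 113 had all probes called the same way and 217 had a call that not all probes shared, 1 of them with opposite directions. Higher and lower probes numbered 330 and 196 without IKKa-null replicate 1, 259 and 174 without IKKa-null replicate 2, 451 and 677 without reconstituted replicate 1, and 208 and 318 without reconstituted replicate 2. The higher share was 48.4%, and 37.9% (350 and 574) under median scaling.

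Pdpn, Cyp1b1, Hspb1, Ddah2, Acta2, Il3ra, Zfp518b, Col4a6, Cd82 and Tiam1 led the genes lower in IKKa-null than in wild-type cells and higher in reconstituted than in IKKa-null cells. Rhox5, Glipr1, Prl2c4, Prl2c3, Birc2, Aldh1a7, Wnt9a, Smoc1, Prl2c2 and Cyp2c55 led those higher and then lower. In all, 230 probes were lower and then higher and 375 higher and then lower. Independent lists of these sizes would share 106 and 120.4 probes. Simulated groups without effect, compared through the same IKKa-null arrays, shared 0.08 and 0.06 on average over 100 draws. Almost nothing is called without effect, so those values do not give the overlap that shared arrays would add to lists of these sizes. Probes moving the same way in both comparisons numbered 46 and 103, against 112.9 and 113.1 for independent lists. Part of the excess may come from the shared IKKa-null arrays, which are too few to be split into sets of 2. With a different single IKKa-null array in each comparison, the log2 changes had a covariance of -0.137 or -0.152 and a correlation of -0.212 or -0.24 across probes. That split shares no array, but it keeps whatever else is particular to the IKKa-null cells. With the shared arrays the covariance was -0.187, against -0.032 simulated without effect, a difference of -0.155, and the correlation was -0.314 against -0.498. The lower-then-higher count was 122 without wild-type replicate 1, 143 without replicate 2, 89 and 62 without IKKa-null replicates 1 and 2, and 101 without reconstituted replicate 2. The higher-then-lower count was 91 and 88 without IKKa-null replicates 1 and 2, and 214 without reconstituted replicate 2. Median scaling gave 98 lower then higher, and detection on all 6 arrays 205 higher then lower.

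**Figure D4:**
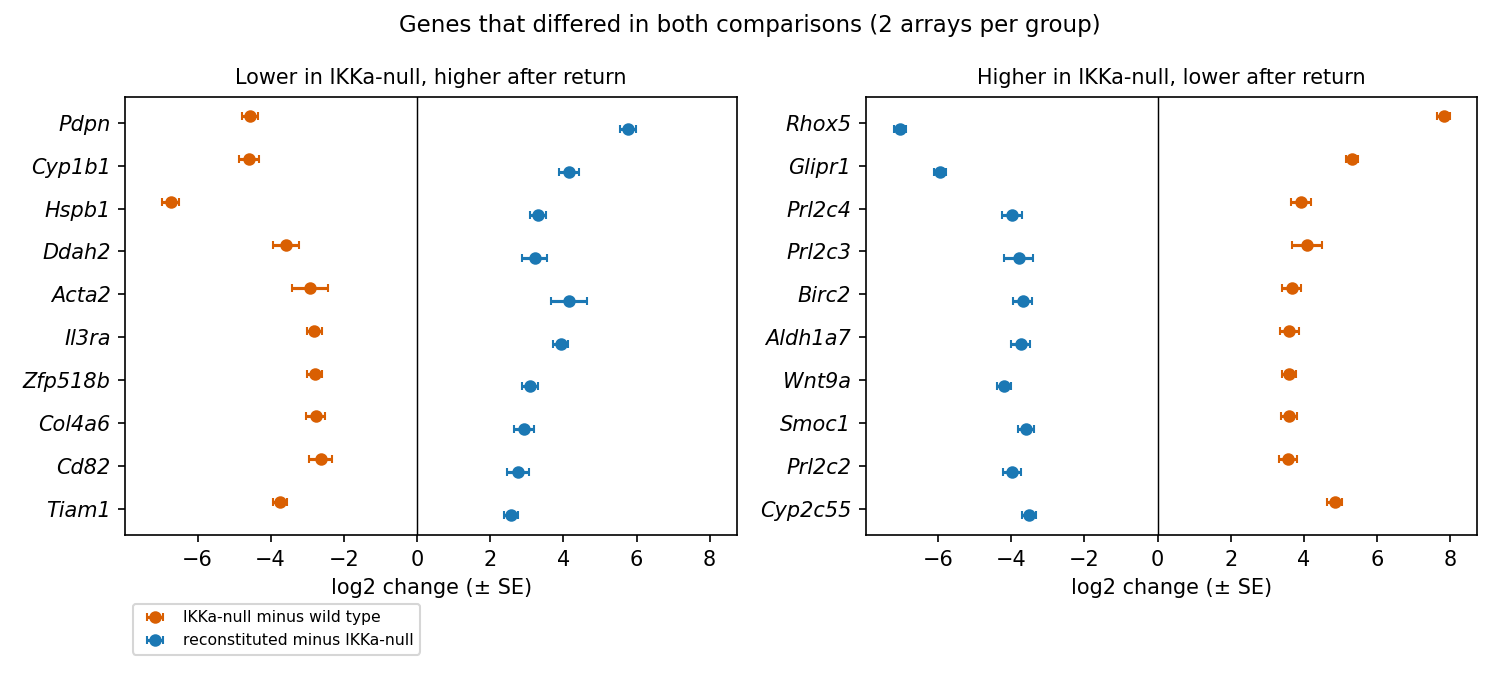
Log2 change (± SE, 2 arrays per group) of the 10 genes per direction that led the probes differing in both comparisons, in IKKa-null minus wild type (orange) and reconstituted minus IKKa-null (blue). Birc2 lies at 3.67 and -3.69 and Ddah2 at -3.58 and 3.22, while genes with a group within background, among them Rhox5, Pdpn and Hspb1, have only a bound and their points are no measured sizes.

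The third comparison asked how far reconstituted cells remained from wild type. Mgp rose from 5.29 ± 0.45 to 12.92 ± 0.44 (log2 signal, mean ± SD, n = 2), at least 100.3-fold (SE 0.293, adjusted p = 2.77e-05). Cldn1, a tight junction protein, rose by at least 34.5-fold, Il33, an alarmin cytokine, by at least 33.8-fold, Esm1 by at least 25.9-fold and Tgfbi, a matrix protein induced by TGF-beta, by at least 29.8-fold. Foxs1, Klra4, Scara3, Fez1, Gap43, Slc14a1 and Crabp1 were the rest of the 12 largest rises. The basement membrane collagens Col4a1 and Col4a2 were lower by at least 19.2-fold and by 33.0-fold (adjusted p = 1.99e-05 and 0.000142). Renbp, Upk3b, Epb41l4a, Hoxb9, En1, Sox11, Parm1, Ptx3 and Sox12, each within background in reconstituted cells, and Gata3, 12.1-fold lower (at least 6.29-fold without reconstituted replicate 1), made up the other large falls. The dimmer group was above background on 1 of its 2 arrays for Gata3, Pttg1, Tgfb2, Ndn, Col3a1, Lpl and Cd14.

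Fibroblast markers were higher than in wild type, with 6 of 10 higher and 0 lower (7 and 1 adjusted over the list alone), a median of 1.25 and a camera adjusted p of 0.0032 (adjusted p = 0.653 with an estimated correlation). Thy1 was 21.3-fold higher, Col3a1 5.32-fold and Pdgfra 3.79-fold. Cholesterol synthesis genes gave 11 higher and 0 lower of 18 (12 and 0 adjusted over the list alone), with a median of 0.70 and a camera adjusted p of 0.00166 (adjusted p = 0.668 with an estimated correlation). Tm7sf2 rose by at least 3.04-fold and Cyp51 2.44-fold (adjusted p = 0.000444 and 0.00694). DNA replication and G1/S genes were called lower than in wild type, with 11 of 29 lower and 1 higher (16 and 2 adjusted over the list alone), a median of -0.52 and a camera adjusted p of 0.0135 (adjusted p = 0.653 with an estimated correlation). Cdc6 fell by 1.38 (adjusted p = 0.00153), while Ccnd1 rose 2.98-fold. The large T target gave 207.8 units in these cells against 5254 in wild type.

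Wnt response genes gave 5 higher and 1 lower of 11 (5 and 1 adjusted over the list alone), with a median of 0.43 and a camera adjusted p of 0.0339 (adjusted p = 0.653 with an estimated correlation). Dkk3 rose 31.2-fold and Tle1, a transcriptional corepressor, 3.84-fold. The call was lost without IKKa-null replicate 1 (median 0.43), reconstituted replicate 1 (0.70) or wild-type replicate 2 (0.30), and the median was 0.65 without reconstituted replicate 2. Collagens and matrix proteins gave 11 higher and 5 lower of 26 (12 and 7 adjusted over the list alone), with a median of 0.65 and a camera adjusted p of 0.0354 (adjusted p = 0.825 with an estimated correlation). The call was lost without wild-type replicate 2 (0.35) or reconstituted replicate 2 (0.60), with median scaling (0.56) or cyclic loess (0.74), and among probes detected on all 6 arrays (0.37). Glycolysis and hypoxia genes gave 4 higher and 0 lower of 21 (1 and 0 adjusted over the list alone), with a median of 0.31 and a camera adjusted p of 0.0288 (adjusted p = 0.825 with an estimated correlation). This was lost without wild-type replicate 2 (0.18) and under median scaling (0.27). Immediate early genes gave 4 higher and 0 lower of 19 (4 and 0 adjusted over the list alone), with a median of 0.86 and a camera adjusted p of 0.0182 (adjusted p = 0.825 with an estimated correlation). Egr3 and Klf4, transcription factors, rose by at least 14.3-fold and 2.27-fold. The call was lost without wild-type replicate 1 (0.91) or reconstituted replicate 1 (0.41) and among probes detected on all 6 arrays (0.72), and the median was 1.38 without reconstituted replicate 2. With fry, the collagen, glycolysis and immediate early lists were not called.

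The other lists were not called against wild type. p53 target genes gave 6 higher and 1 lower of 15 (6 and 1 adjusted over the list alone, camera adjusted p = 0.251), with Ccng1 2.31-fold higher. Cdkn2a, a list member that encodes the tumour suppressors p16 and p19 and is no p53 target itself, was 4.13-fold lower. The p53 list was called without reconstituted replicate 2 (median 0.68, against 0.22). NF-kB target genes gave 1 higher, Tnfaip2, and 0 lower of 24 (0 and 0 adjusted over the list alone, adjusted p = 0.631), and were called without reconstituted replicate 2 (median 1.10, against 0.18). Tnfaip2 rose by 1.504 and was not called without wild-type replicate 2 (1.35). Noncanonical targets gave 0 higher and 2 lower of 5 (0 and 2 adjusted over the list alone, adjusted p = 0.46), and IKK and NF-kB pathway members 1 higher and 4 lower of 13 (1 and 4 adjusted over the list alone, adjusted p = 0.387). Interferon-stimulated genes gave 2 higher and 1 lower of 16 (2 and 0 adjusted over the list alone, adjusted p = 0.828). Their median and mean, -0.27 and -0.05, were below 0 while camera put the list above other genes. Ifit3 rose by at least 4.06-fold. Antigen presentation genes gave 0 higher and 1 lower of 10 (0 and 1 adjusted over the list alone, adjusted p = 0.631). Mitosis genes gave 1 higher and 4 lower of 20 (1 and 4 adjusted over the list alone, adjusted p = 0.317), with Plk1 8.13-fold higher and Pttg1 9.04-fold lower, and were called with no filter and with fry. Matrix proteases and inhibitors gave 4 higher and 1 lower of 14 (4 and 1 adjusted over the list alone, adjusted p = 0.0585), with Mmp2 6.19-fold higher. That list was called without IKKa-null replicate 2 (median 0.399) or reconstituted replicate 2 (0.45), among probes detected on all 6 arrays (0.66), without background correction, with normexp and with the series matrix values.

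Smooth muscle and myofibroblast genes gave 2 higher and 1 lower of 9 (3 and 1 adjusted over the list alone, adjusted p = 0.321). Nrf2 and glutathione genes gave 2 higher and 5 lower of 19 (3 and 5 adjusted over the list alone, adjusted p = 0.844), and TGF-beta and BMP response genes 5 higher and 8 lower of 19 (5 and 8 adjusted over the list alone, adjusted p = 0.94). Tgfb2 was 6.03-fold lower and Grem1, an antagonist of BMPs, 3.48-fold higher. For unfolded protein and amino acid stress genes the counts were 4 higher and 3 lower of 22 (3 and 2 adjusted over the list alone, adjusted p = 0.977). Their median was -0.22 and their mean -0.13, while camera put the list above other genes. Ribosomal proteins gave 2 higher and 2 lower of 28 (2 and 2 adjusted over the list alone, adjusted p = 0.631). Hox and positional genes gave 7 higher and 4 lower of 17 (7 and 5 adjusted over the list alone, adjusted p = 0.791). Their median was -0.22 and their mean -0.14, while camera put the list above other genes. Imprinted genes gave 3 higher and 5 lower of 11 (3 and 6 adjusted over the list alone, adjusted p = 0.593), with Ndn 7.09-fold lower (at least 3.85-fold without reconstituted replicate 1). With fry, the imprinted list and the ribosomal proteins were called.

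Among markers of other cell types, 3 of 4 epithelial markers were lower, Krt14 and Krt19 by at least 3.27-fold and at least 3.14-fold. Of 3 skeletal muscle markers 2 were lower and 1 higher, of 3 chondrocyte and osteoblast markers 2 were higher and 1 lower, and of 2 endothelial markers Eng was higher and Flt1 lower. Flt1 was not called without wild-type replicate 1 (-0.73) or reconstituted replicate 2 (-0.78). The 1 adipocyte marker, Lpl, was 3.54-fold lower. Neither the 1 macrophage and blood marker (Cd14, 0.16) nor the 2 neural and glial markers (Nes, 0.12, and Tubb3, -0.13) was called. The sign turned for Cd14 and Nes without wild-type replicate 1 (-0.50 and -0.19) and without reconstituted replicate 1 (-0.20 and -0.28). All 3 sex-linked genes were called, with Xist lower by at least 5.01-fold and Eif2s3y higher by at least 3.50-fold. Actb and Gapdh changed by -0.43 and 0.18 (adjusted p = 0.0886 and 0.474).

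Reconstituted cells differed from wild type at 2033 higher and 2214 lower probes (36.4%), of which 1270 and 1013 differed by at least 2-fold. At least 1 probe was higher for 1277 genes and lower for 1740. Of 1748 genes with several probes, 358 had all probes called the same way and 577 had a call that not all probes shared, 17 of them with opposite directions. The higher share was 47.9%, 51.2% under median scaling (1211 and 1153) and 56.5% with cyclic loess. Higher and lower probes numbered 1457 and 1155 without wild-type replicate 1, 1161 and 790 without wild-type replicate 2, and 1355 and 1367 without reconstituted replicate 2. Of the 1746 probes higher in IKKa-null cells, 375 (21.5%) fell in reconstituted cells and 1138 (65.2%) were also called higher in reconstituted than in wild-type cells. Of the 1637 lower probes, 230 (14.1%) rose and 1033 (63.1%) were also called lower. Independent lists would share 304.5 and 310.9 probes and simulated groups without effect shared 0.03 and 0.08, but the first value leaves out the wild-type arrays that both comparisons use and the second the effects, so part of the excess may come from those arrays. The covariance of the 2 sets of log2 changes was 0.524, against 0.032 simulated without effect, a difference of 0.492. With a different single wild-type array in each comparison it was 0.474 or 0.501. That split shares no array, but it keeps whatever else is particular to the wild-type cells, among it the large T signal. An effect called in 1 comparison and not in another was not tested for a difference between them.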

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

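All tests weighed in this part were chosen after the results had been seen. Outside the genes compared, 6 of 35 construct targets and 9 of 287 numbered targets gave signals above background on every array of at least 1 group. The highest group means were as follows. SV40 large T reached 5253.9 intensity units and the target common to both T antigens 2400.4, both in wild type. Ampicillin resistance reached 621.2 in wild type, and neomycin resistance 3048.1 in reconstituted cells. The 5′ long terminal repeat of Moloney murine sarcoma virus reached 3392.8 and the extended packaging signal 225.1, both in IKKa-null cells. The long terminal repeat was 18.75-fold lower in reconstituted than in IKKa-null cells, and 7 of the numbered targets were 7.11-fold to 33.4-fold lower, so these 2 groups also differ in viral sequence and in targets of unknown identity. The target with the 33.4-fold difference was above background on only 1 of the 2 reconstituted arrays (186 and 134.6 units). Of the numbered targets, whose identity is not analysed here, 8 were highest in IKKa-null cells, at 7094.2, 8749.5, 10593.3, 9142.2, 12115, 8187.4, 2269.4 and 168.2, and 1 in reconstituted cells, at 222.1.

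The large T signal in wild-type cells bears on the p53 and replication lists, which moved in IKKa-null cells. Loss of IKKa that its return undoes is argued against for replication genes, whose median was 0.091 in reconstituted minus IKKa-null cells. This holds only as far as IKKa was restored. That could not be checked, because no probe carries the symbol Chuk in the annotation used. Large T in wild type may account for the replication genes: they lay at -0.52 in reconstituted minus wild-type cells. For p53 targets, return of IKKa is a candidate explanation, with a median of -0.783 in reconstituted minus IKKa-null cells. Large T cannot be told apart from it there. The median in reconstituted minus wild-type cells was 0.218, under the bound set for large T, which goes against large T. It was 0.725 on the arrays numbered 1, over the bound, and -0.059 on those numbered 2. A large T signal also remained in reconstituted cells, 47.0-fold below wild type after normalization. Whether so weak a signal acts on p53 was not tested. The reading for replication genes takes it as too weak to act, so these readings rest on unlike assumptions. Against wild type, Xist was lower and Eif2s3y and Kdm5d were higher in both other groups. Wild-type cells thus differ from the others in more than IKKa, and absence of IKKa cannot be told apart from those differences. The viral sequences that separate IKKa-null from reconstituted cells leave other differences between those cells open and untested.

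Birc2, Birc3, Yap1, Cfap300 and Cep126, 5 tested neighbours on chromosome 9, were all higher in IKKa-null cells, the smallest by 2.109 in normalized log2 signal, no measured size because Cep126 was within background elsewhere. In 10000 shuffled gene orders the highest such run was 1.95 (permutation p of 1e-04, the smallest these shuffles can give), but this rests on that unmeasured size and on a run length of 5 set after the run had been seen. With bounds in place of sizes within background, the 5 reached 0.686 against a shuffled median of 0.655 (permutation p = 0.38, and 0.9 over 6 run lengths). Chance placement thus stays open for all 5. Birc2 to Cfap300 reached 1.808 (permutation p = 0.0063 over 6 run lengths). In reconstituted against IKKa-null cells, which shares the IKKa-null arrays, the same test gave 0.15 for the 5 and 0.0018 for Birc2 to Cfap300. Runs on chromosome 5, counted in either direction, gave 0.0057 (Anapc5 to Vps33a) and 7e-04 (Cdk2ap1 to Tctn2) in IKKa-null against wild-type cells. All tested genes of that chromosome had a median of -0.516 in this comparison, against -0.117 over all placed genes, so these runs lie within a wider shift. Neighbouring genes are not independent, which makes these p-values too small. Yap1 was above background on all arrays. Its 8.74-fold rise argues against cross-hybridisation between the paralogs Birc2 and Birc3 as the source of the whole run. It does not show whether the Birc2 and Birc3 probes read each other's transcripts. At -0.33 in reconstituted minus wild-type cells, Yap1 argues against extra copies shared by IKKa-null and reconstituted cells. The median of -0.015 does not, since 3 of the 5 genes were within background in both reconstituted and wild-type cells. A loss of IKKa that its return undoes is consistent with Yap1 at -3.45 in reconstituted minus IKKa-null cells (the median, -3.442, is that of Cfap300, no measured size), but extra copies in the IKKa-null cells alone would give the same value and were not tested.

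NF-kB target genes were called higher in IKKa-null cells, yet they also differed between the arrays numbered 1 and 2 of every group. In each group that difference lay at percentile 100 of 10000 random lists matched on mean expression, which shows that the numbered arrays differ, not why the groups do. Among the arrays numbered 2 the median was -0.213 in IKKa-null minus wild-type cells, against 1.738 among those numbered 1. An effect of IKKa loss and a difference between the individual samples cannot be told apart, because each number leaves 1 array per group.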

How the results depend on the processing

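Spike controls alone and arrays of 1 replicate number were chosen after the data had been seen, and the other alternatives before. The counts of probes kept within 1.5 times their values without background correction, with normexp, cyclic loess, no filter, the series matrix, only the compared groups, trended robust eBayes and spike controls alone. The calls of 330 named gene values held in 278 cases under median scaling and 314 with cyclic loess, and of 21 called list medians in 17 and 19. The replicate numbers share no stated link, and replicate differences correlated across probes by 0.298, 0.051 and 0.37. With the replicate number as a block, 1885 higher and 1741 lower, 822 and 872, and 2183 and 2342 probes were called in the 3 comparisons, and the Wnt list lost its call in reconstituted against wild-type cells while the NF-kB list gained one in reconstituted against IKKa-null cells. Of 8 log2 differences of construct targets, 6 moved without background correction and with the series matrix and 5 with normexp, none with a turned sign, so their sizes depend on the background correction. With no filter the epithelial markers, then enough to be tested, were called lower in reconstituted against wild-type cells. Chuk was not analysed, the files give no slide to use as a block, and the lists were not run on only the compared groups. Signal near background limits the values of dim probes, for which folds are bounds.

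At an adjusted p under 0.01 the higher and lower counts were 859 and 545 (IKKa-null against wild type), 305 and 281 (reconstituted against IKKa-null) and 1115 and 923 (reconstituted against wild type), with 76 and 173 for probes lower then higher and higher then lower. Requiring a 2-fold change gave 1108 and 717, 498 lower, 1270 and 1013, and 131 lower then higher. These follow from the stricter thresholds. Median scaling gave 562 lower, 350 higher, 1211 and 1153, and 98 lower then higher, and detection on all 6 arrays, with fewer probes tested, gave 205 higher then lower. With an estimated correlation 0 lists passed in each comparison, against 8, 6 and 7, and with fry 6, 6 and 7 did, including 12 of the 21 calls. The cause was not tested, except that an estimated correlation leaves camera 3 degrees of freedom. The estimated correlation was 0.872 for interferon-stimulated genes, 0.707 for NF-kB targets, 0.595 for immediate early genes and 0.384 for glycolysis genes. It was 0.268 for collagens and matrix proteins, 0.187 for cholesterol synthesis genes, 0.139 for fibroblast markers and 0.123 for p53 targets. Matrix proteases gave 0.061, Wnt response genes 0.03 and Nrf2 genes -0.021. Replication and mitosis genes gave 0.022 and -0.033. For lists far over the preset 0.01, the adjusted p with the preset may be too small.

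Leaving out 1 array, which leaves fewer samples, gave 822 to 1831 higher and 465 to 1775 lower in the first comparison. The ranges were 208 to 598 and 174 to 677 in the second and 1161 to 1858 and 790 to 1963 in the third. Probes lower then higher ranged from 62 to 182, and higher then lower from 88 to 325. Called lists ranged from 3 to 8, 5 to 8 and 4 to 9, with 3 without IKKa-null replicate 1 and 4 without wild-type replicate 2.

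Signs turned for few values, mostly near 0, and the cause was not tested. In IKKa-null against wild type, Lpl (-0.01) was 0.096 with median scaling, 0.09 with cyclic loess and -0.415 to 0.396 with 1 array left out. In reconstituted against IKKa-null, Gapdh (0.00) was -0.078 with median scaling, -0.001 with the series matrix and -0.111 to 0.124 with 1 array left out, and Xist (0.02, within background in both groups) -0.162 to 0.198. In reconstituted against wild type, Cd14 (0.16) ranged from -0.497 to 0.81 and Nes (0.12) from -0.285 to 0.532. The NF-kB list in IKKa-null against wild type ranged from -0.534 to 2.257, with -0.213 on the arrays numbered 2 alone, where the immediate early list was at -0.156.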

Other observations

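Targets for mitochondrial DNA transcripts, chosen after the data had been seen, were on no list. Of 11 tested, 6 were higher and 0 lower in IKKa-null than in wild-type cells, with a median log2 change of 0.56. Of the same 11, 0 were called in reconstituted against IKKa-null cells (median -0.06) and 5 were higher in reconstituted than in wild-type cells (0.59).

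All tests in this part were chosen after the results had been seen. Genes of some chromosomes shifted together. In IKKa-null against wild-type cells the median of all placed genes was -0.12, while genes of chromosome 5 lay at -0.52 and those of chromosome 17 at -0.37, and genes of chromosomes 14 and 12 above it at 0.20 and 0.18. In reconstituted against wild-type cells, with -0.14 over all genes, chromosome 15 lay at -0.45 and chromosome 5 at -0.43, and chromosomes 6 and 12 at 0.09 and 0.08. In reconstituted against IKKa-null cells, with -0.02 over all genes, chromosomes 14 and 15 lay at -0.28 and chromosomes 19 and 6 at 0.21 and 0.20. By permutation, 14, 15 and 15 of 20 chromosomes differed from shuffled genes in the 3 comparisons, though neighbouring genes are not independent, which makes these p-values too small. In reconstituted against wild-type cells the strongest run of 5 neighbours, from Cptp to Sdf4 on chromosome 4, lay lower, the least changed, Sdf4, within background in reconstituted cells, and 341 of 10000 shuffled orders held a run as large.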
